A study of Mus musculus with 3 samples.

How the data were processed

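Poly(A) RNA of 3 pooled mouse samples was captured with poly-T beads, made into TruSeq libraries and sequenced on an Illumina instrument, per the labels. The authors deposited 1 table per library with an FPKM value and a status for each gene. TopHat 1.4.1, Cufflinks 1.3.0 and the mouse build mm9 are named in the submitters' processing notes, without their role, and the annotation release is not given in the sources used here. The reference at hand was of another build, so no coordinates are given. Its symbol table matched 20773 of the 22378 gene identifiers and was used only for list symbols. Where a list symbol was not among the gene names, the gene model with that current symbol stood in. Examples are 1600029D21Rik for Plet1 and H2-Gs10 for H2-Q4.

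No value was given for 78 genes in any library. The status was OK for 22245 genes in LCC, 22234 in E-Int29-Hi and 22237 in MG. Only the 22188 genes with status OK in all 3 libraries were used, and 112 with a value were left out for their status. Where a gene name stood on several of these gene models (105 names), the model with the highest FPKM summed over the libraries was kept, which left 22077 names. FPKM values summed to 377918 in LCC, 330432 in E-Int29-Hi and 291133 in MG, and the mitochondrially encoded genes held 5.91%, 4.79% and 5.77% of these sums.

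Read counts were not given, so relative depth was read from the low values. A gene with few reads has values in steps that depend on depth, and the commonest ratio among genes under 0.1 FPKM was 1.13 for LCC over E-Int29-Hi (24 of 408 genes), 1.17 for LCC over MG (19 of 348) and 1.05 for E-Int29-Hi over MG (136 of 1198). Genes listed at 0 numbered 6871 in LCC, 4984 in E-Int29-Hi and 3184 in MG. Of 1086 olfactory receptor genes, 9, 35 and 282 stood above 0 in LCC, E-Int29-Hi and MG, with lowest values of 0.123, 0.00726 and 0.00595 FPKM and medians of 0.193, 0.0254 and 0.0237 FPKM. These differ between LCC and MG by far more than the commonest ratio, which rests on few genes and on values under 0.1 FPKM in both libraries, so the size of the depth difference stays unsettled. A value of 0 can be a failed estimate and is described only as listed at 0, without a fold.

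For each pair of libraries, log2((FPKM + 1)/(FPKM + 1)) was computed for genes at 1 FPKM or more in at least 1 of them, and genes with a value of 2 or more in size were counted. With 1 library per group no test was run and no p-value is given. For each of 41 gene lists, the median over members passing the same filter was compared with 10000 random lists of the same size drawn from 20 bins of mean log2 expression. The percentile describes these libraries and is not a test across animals. Of 764 distinct list genes, 18 were not among the gene names analysed. They include Egr2 and Vegfa, which had values but were left out for their status.

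The lists, measure, filter and naming rule were fixed before the data were examined. The rule named the 12 highest and 12 lowest log2 changes per comparison among genes at 10 FPKM or more in the higher library, leaving out small RNA, unnamed and pseudogene models. It also named Epcam, Itgb1, up to 4 members of each list with the highest FPKM, and any list member at least 4-fold apart. Genes outside the rule are said to be chosen after their values were seen. The alternatives fixed at the same time were a pseudocount of 0.1 or 5, no low-value filter or one at 5 FPKM, scaling by median ratios, rescaling to the same sum per library (TPM), and summing models of one name. Alternatives added after the data were seen kept genes of every status, left out genes listed at 0, or left out the lung epithelium, leukocyte, platelet and erythroid lists.

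The steps were tested on simulated data, a pair of libraries made from MG with 12186 genes. Both were drawn from the same profile with counting noise alone, and only genes at 10 FPKM or more were changed. At a true fold of 2 or 3, 0 of 50 genes each were called, and at 8 or 16, 50 of 50 each, with 0 of 11986 unchanged genes called. Of 100 unchanged lists, drawn at random, 6 lay outside the central 95%. The simulation checks the computation only. It gives no error rate for separate pools of cells, for changes in low genes or for lists of related genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.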

Results

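Gene expression was measured by RNA sequencing in mammary cells of FVB mice, in 3 libraries with 1 library per group. The first library held lung-colonizing cells (LCC), which are mammary cells that were injected into a vein of recipient mice and sorted from the dissociated lungs 1 day later. In each experiment, cells of 8 donor mice were given to 4 recipients in 2 injections of 2500000 cells. Injected cells were recognised by green fluorescent protein or by the dye DDAO, and the LCC library pooled 15 experiments, 42 lungs and 455880 cells. This sort had no EpCAM or CD29 gate. The second library (E-Int29-Hi) held mammary cells sorted for intermediate EpCAM and high CD29 on their surface, a gate labelled as enriched for the colonizing cells, from 3 combined samples. The third library (MG) was labelled as mammary gland that had not been dissociated, from 3 combined samples. The stated purpose was to describe the LCC profile and to find genes that differ between these populations.

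Each library listed 22378 genes as FPKM (fragments per kilobase of gene model, scaled to the number of mapped fragments). Of the gene names analysed, 11298 stood at 1 FPKM or more in LCC, 11033 in E-Int29-Hi and 12024 in MG. Total read numbers were not given in the sources used here. There were no replicates, so no difference below has a replicate check, and every value describes these pooled libraries. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and genes counted as higher or lower are at least 4-fold apart on that scale. The median of each gene list was set against 10000 random lists of the same size matched on mean expression. Of 122 list medians, 69 lay outside the central 95% of their random lists, where 6.1 would be expected of lists drawn at random. The fixed lists hold related genes, some share members, and the comparisons share libraries. The excess is therefore a description and not a test.

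The genes behind the sorting gate were abundant in all 3 libraries. Epcam, an epithelial adhesion molecule, stood at 325 FPKM in LCC, 279 in E-Int29-Hi and 209 in MG. Itgb1, which encodes CD29, stood at 401, 296 and 198 FPKM in the same order. Across genes, which are not independent replicates, the correlation of log2 levels was higher between LCC and MG (Pearson r = 0.860) than between LCC and E-Int29-Hi (r = 0.766), with r = 0.832 between E-Int29-Hi and MG.

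**Figure D1:**
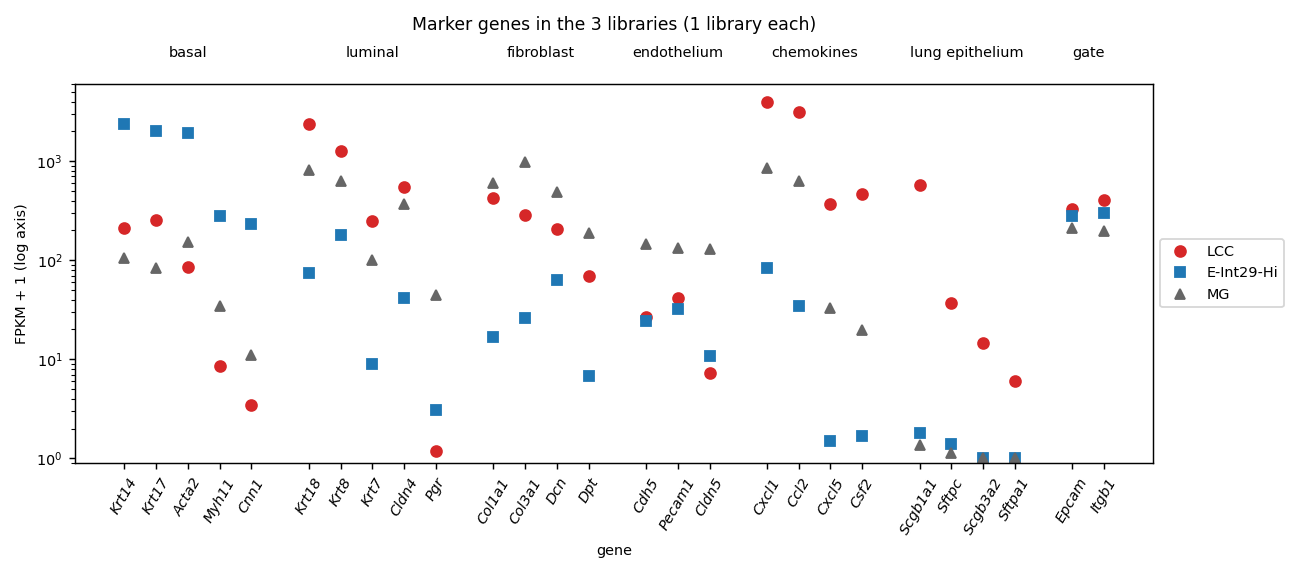
Level of marker genes (FPKM + 1, log axis) in the LCC, E-Int29-Hi and MG libraries, with 1 point per library and no error bars because there were no replicates. Basal genes such as Krt14 are highest in E-Int29-Hi (2380.5 FPKM), whereas Krt18 (2368 FPKM), Cxcl1 (3938 FPKM) and Scgb1a1 (572 FPKM) are highest in LCC.

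The comparison of LCC with E-Int29-Hi set cells recovered from the lung beside the gated population labelled as containing them. Genes of the basal, contractile layer of the mammary epithelium were far lower in LCC. The medians of the luminal, fibroblast, chemokine and matrix protease lists lay above all random lists, with 10 of 24, 11 of 20, 18 of 28 and 10 of 25 members higher. Of 12147 genes at 1 FPKM or more in either library, 564 were higher and 528 lower in LCC, and the median gene stood 0.26 (log2) higher. With each library scaled by its median ratio (divisors of 1.08 for LCC and 0.892 for E-Int29-Hi), 447 genes were higher and 685 lower. Rescaled to the same sum per library (TPM) without mitochondrial, small RNA and unnamed genes, 794 were higher and 872 lower. TPM values are larger than the deposited ones, so with the same pseudocount more low genes pass, and TPM counts are not on the same footing.

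Among 24 basal and myoepithelial genes, 18 were lower in LCC and 0 higher, and the median log2 change of -3.01 lay below all random lists. The basal keratin genes Krt14 and Krt17 stood at 209.8 against 2380.5 FPKM and at 251 against 2029 FPKM. Trp63, a transcription factor of basal epithelium, stood at 6.41 against 46.0 FPKM, and Itga6, an integrin subunit of basal cells, at 26.8 against 351 FPKM. The contractile list, which shares several genes with the basal list, had 10 of 19 members lower and 0 higher. Acta2, smooth muscle actin, stood at 84.2 against 1901 FPKM, Myh11, smooth muscle myosin, at 7.53 against 278 FPKM, and Cnn1, calponin, at 2.44 against 233 FPKM. Of 19 basement membrane genes, 5 were lower and 0 higher (median -0.74, 0.12th percentile), with the laminin gene Lama1 at 0.765 against 32.3 FPKM.

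Of 24 luminal genes, 10 were higher in LCC and 0 lower, with a median of 1.12 above all random lists. Krt18 stood at 2368 against 73.5 FPKM, Krt8 at 1258 against 179.7 FPKM, Krt7 at 249 against 7.96 FPKM and Cldn4, a tight junction gene, at 549.8 against 40.2 FPKM. The hormone receptor genes Esr1 and Pgr, members of this list, stood at 0.734 against 3.06 FPKM and at 0.179 against 2.07 FPKM. Of 12 milk protein genes, 4 were lower and 0 higher, including Lcn2, a siderophore-binding protein, at 55.2 against 2148 FPKM.

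Of 20 fibroblast genes, 11 were higher in LCC and 0 lower (median 2.20, above all random lists), with Col1a1 at 427 against 15.9 FPKM and Col3a1 at 283 against 25.1 FPKM. Of 17 genes of the epithelial-mesenchymal transition and mesenchymal cells, 11 were higher and 1, Snai2, was lower (median 2.82, above all random lists). They included Vim (1638 against 154 FPKM), Tnc (379.8 against 8.39 FPKM), Twist2 (39.2 against 0.329 FPKM) and Zeb2 (34.2 against 2.17 FPKM), which fibroblasts also express. Against MG, this list had a median of 0.16 in LCC (41.2nd percentile, 2 of 17 higher and 0 lower). Its median in E-Int29-Hi against MG was -1.76, with 7 of 17 lower and 1 higher. Of 19 endothelial genes, 0 were higher and 1, Vwf, was lower, and the median of -0.10 lay at the 9.28th percentile.

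Among 28 chemokines and inflammatory cytokines, 18 were higher in LCC and 1, Cxcl12, was lower, with a median of 2.91 above all random lists. Cxcl1, a neutrophil attractant, stood at 3938 against 83.1 FPKM, and Ccl2, a monocyte attractant, at 3106 against 33.4 FPKM. Csf2, which encodes GM-CSF, stood at 464 against 0.694 FPKM, Cxcl5 at 365 against 0.506 FPKM, Cxcl3 at 284 against 0.454 FPKM and Il6 at 613 against 43.1 FPKM. Of 25 extracellular matrix proteases and inhibitors, 10 were higher and 0 lower, and 7 stood below E-Int29-Hi by less than 4-fold, including Adamts1 (log2 change -1.19). Mmp3 stood at 278 against 0.587 FPKM, Mmp12 at 111 against 0.495 FPKM and the plasminogen activator gene Plau at 265 against 34.3 FPKM. Serpinb2, an inhibitor of plasminogen activators, stood at 151 against 0.584 FPKM, Inhba, an activin subunit, at 248 against 4.02 FPKM, and Il1rl1, the receptor of interleukin 33, at 220.0 against 0.5004 FPKM.

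Lists of lung and blood cell markers also had members higher in LCC. Of 16 lung epithelium genes, 7 were higher and 0 lower, with a median of 1.73 above all random lists. Scgb1a1 (ENSMUSG00000024653), the secretoglobin of airway club cells, gave the largest log2 increase of the named genes (8.32), at 572 against 0.798 FPKM. Sftpc, a surfactant protein of alveolar type II cells, stood at 36.3 against 0.390 FPKM. Of 19 macrophage and monocyte genes, 7 were higher and 0 lower, with Ctss, a lysosomal protease, at 162 against 9.34 FPKM. The neutrophil list had 5 of 9 members higher and 1, Lcn2, lower. The rest of its 21 members stood under 1 FPKM in both libraries, with Ly6g, Ngp, Camp, Mpo and Cxcr2 listed at 0 in LCC. Of 5 erythroid genes, 4 were higher, namely the globin genes Hba-a1 (17.5 against 1.27 FPKM), Hba-a2, Hbb-b1 and Hbb-b2. These are near-identical copies, so their separate values are uncertain.

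The largest decreases included Chi3l1 (14.1 against 1305 FPKM), the collagen gene Col9a2 (0.310 against 132 FPKM) and the Wnt inhibitor gene Wif1 (1.25 against 107 FPKM). Psp (0.358 against 147 FPKM) and Dcpp1 (0.0470 against 63.8 FPKM), secreted products known from salivary glands, were also among them; Dcpp1 has near-identical copies. A gene model named Uck2 (ENSMUSG00000053664) was listed at 0 in LCC and at 909.6 FPKM in E-Int29-Hi, while a second model of that name (ENSMUSG00000026558) stood at 39.7 against 33.9 FPKM. In the list of Notch, Wnt, Hedgehog and stem or progenitor genes, 5 of 25 members were lower and 0 higher. Sox10 stood at 15.0 against 215 FPKM, Lgr5 at 0.659 against 19.8 FPKM and Wnt10a at 1.66 against 40.2 FPKM.

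The comparison of LCC with MG set the recovered cells beside the gland. The medians of the chemokine, lung epithelium and macrophage lists lay above all random lists. Those of the milk protein, luminal, endothelial and interferon-response lists lay below all random lists. Among 12443 genes, 166 were higher and 327 lower, and the median gene differed by 0.01 (log2). Median ratio scaling gave 138 higher and 335 lower, and TPM gave 174 higher and 848 lower.

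Of 28 chemokines and cytokines, 8 were higher in LCC than in MG and 0 lower (median 1.25, above all random lists). Cxcl1 stood at 3938 against 852 FPKM, Ccl2 at 3106 against 626 FPKM, Csf2 at 464 against 18.7 FPKM and Cxcl5 at 365 against 31.9 FPKM. Ccl17 (47.0 against 0.997 FPKM), Ccl22 (53.5 against 1.61 FPKM), Il12b (28.4 against 0.658 FPKM) and Il23a (40.0 against 1.47 FPKM), cytokine genes known from dendritic cells, were among the 12 largest increases. Of 25 matrix proteases and inhibitors, 8 were higher and 0 lower (98.8th percentile), with Mmp9 at 33.6 against 1.32 FPKM and Timp1 at 352 against 24.3 FPKM. Inhba stood at 248 against 13.3 FPKM and Serpinb2 at 151 against 5.79 FPKM. Of 16 lung epithelium genes, 8 were higher and 1, Aqp5, was lower, with Scgb1a1 at 572 against 0.352 FPKM. Of 21 macrophage and monocyte genes, 5 were higher and 0 lower, with Lyz2, lysozyme, at 232 against 28.5 FPKM.

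Of 13 milk protein genes, 10 were lower in LCC than in MG and 0 higher (median -3.35, below all random lists), with the casein gene Csn3 at 19.5 against 466 FPKM and Lalba, lactalbumin, at 0.0375 against 94.2 FPKM. Of 23 luminal genes, 7 were lower and 0 higher (median -0.997, below all random lists). Pgr, the progesterone receptor, stood at 0.179 against 43.9 FPKM, Prlr, the prolactin receptor, at 1.5 against 39.4 FPKM, and Prom1 at 0.772 against 18.9 FPKM, whereas Krt18 stood at 2368 against 819 FPKM. Krt4 (0.0761 against 102 FPKM) and Cited1 (0.0480 against 58.7 FPKM) were among the largest decreases. The basal list had 1 of 23 members higher, Lamb3, and 2 lower, Myh11 and Oxtr, and its median of -0.31 lay at the 1.21st percentile. Krt14 stood at 209.8 against 104 FPKM.

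Of 19 endothelial genes, 7 were lower in LCC than in MG and 0 higher (median -1.70, below all random lists), with Cdh5 at 25.9 against 145 FPKM and Cldn5 at 6.23 against 128 FPKM. Of 20 fibroblast genes, 2, Pi16 and Gsn, were lower and 0 higher, and the median of -0.89 lay below all random lists. Col1a1 stood at 427 against 598 FPKM. Of 21 interferon-response genes, 4 were lower and 0 higher (median -1.23, below all random lists), including Usp18 (0.426 against 7.66 FPKM), and 6 members stood above MG by less than 4-fold. Among 24 proliferation genes, 0 were higher and 0 lower, but the 4-fold rule needs 3 FPKM, which many of them reached in neither library. By any amount, 18 stood below MG and 6 above, with 5 at least 2-fold lower and 2 at least 2-fold higher (median -0.50, 9.7th percentile). Mki67 stood at 1.19 against 4.00 FPKM, Top2a at 1.21 against 5.37 FPKM, Mcm2 at 8.74 against 3.28 FPKM and Pcna, the DNA polymerase clamp, at 44.6 against 46.5 FPKM.

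The comparison of E-Int29-Hi with MG set the gated population beside the gland. The medians of the basal and contractile lists lay above all random lists, and those of the luminal, fibroblast, endothelial and milk protein lists lay below all of them. Among 12430 genes, 323 were higher and 494 lower, and the median log2 change was -0.23. Median ratio scaling gave 392 higher and 415 lower, and TPM gave 372 higher and 1021 lower.

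Of 23 basal genes, 16 were higher in E-Int29-Hi than in MG and 0 lower (median 3.00, above all random lists), and 10 of 19 contractile genes were higher and 0 lower. Krt14 stood at 2380.5 against 104 FPKM, Krt17 at 2029 against 82.5 FPKM, Acta2 at 1901 against 151 FPKM and Cnn1 at 233 against 9.96 FPKM. Of 19 basement membrane genes, 6 were higher and 2, Nid1 and Nid2, were lower, with Lama1 at 32.3 against 1.67 FPKM. In the Notch, Wnt, Hedgehog and stem or progenitor list, 4 of 25 members were higher and 3 lower, with Sox10 at 215 against 24.5 FPKM and Wnt10a at 40.2 against 1.32 FPKM. Of 24 luminal genes, 16 were lower and 0 higher (median -2.91, below all random lists), including Krt18 (73.5 against 819 FPKM) and Aldh1a3 (1.17 against 71.8 FPKM). Of 13 milk protein genes, 8 were lower and 1, Lcn2, was higher.

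Of 20 fibroblast genes, 15 were lower in E-Int29-Hi than in MG and 0 higher (median -2.82, below all random lists), with Col3a1 at 25.1 against 978 FPKM and Thbs2, a thrombospondin, at 2.14 against 276 FPKM. Of 19 endothelial genes, 7 were lower and 0 higher, with Cdh5 at 23.1 against 145 FPKM. Of 27 chemokines and cytokines, 11 were lower and 0 higher, with Cxcl1 at 83.1 against 852 FPKM. Of 21 interferon-response genes, 7 were lower and 0 higher, and the median of -1.65 lay below all random lists. Psp (147 against 0.121 FPKM), Smr3a (82.0 against 0.0367 FPKM) and Dcpp1 (63.8 against 0.337 FPKM) gave the largest increases of the named genes. Pdk4, a kinase that inhibits pyruvate dehydrogenase, stood at 254 against 11.7 FPKM, and at 231 FPKM in LCC. The metallothionein genes Mt1 and Mt2 stood at 4624 against 560.0 FPKM and at 3072 against 565 FPKM.

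Adipoq, the hormone adiponectin, chosen after its values were seen, stood at 1.12 FPKM in MG, and Car3, an adipocyte carbonic anhydrase, at 18.9 FPKM. Fabp4, which endothelium also expresses, stood at 845 FPKM in MG, 276 in E-Int29-Hi and 60.4 in LCC. Genes of the immediate early and dissociation response were abundant in each library, with Fos at 94.7, 369 and 604 FPKM and Junb at 329, 614 and 453 FPKM in LCC, E-Int29-Hi and MG. That list's median was -0.65 for LCC against MG, below all random lists, with 18 of 21 members lower by any amount and 3 higher. For E-Int29-Hi against MG it was -0.26 (0.545th percentile), with 12 lower by any amount and 9 higher.

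**Figure D2:**
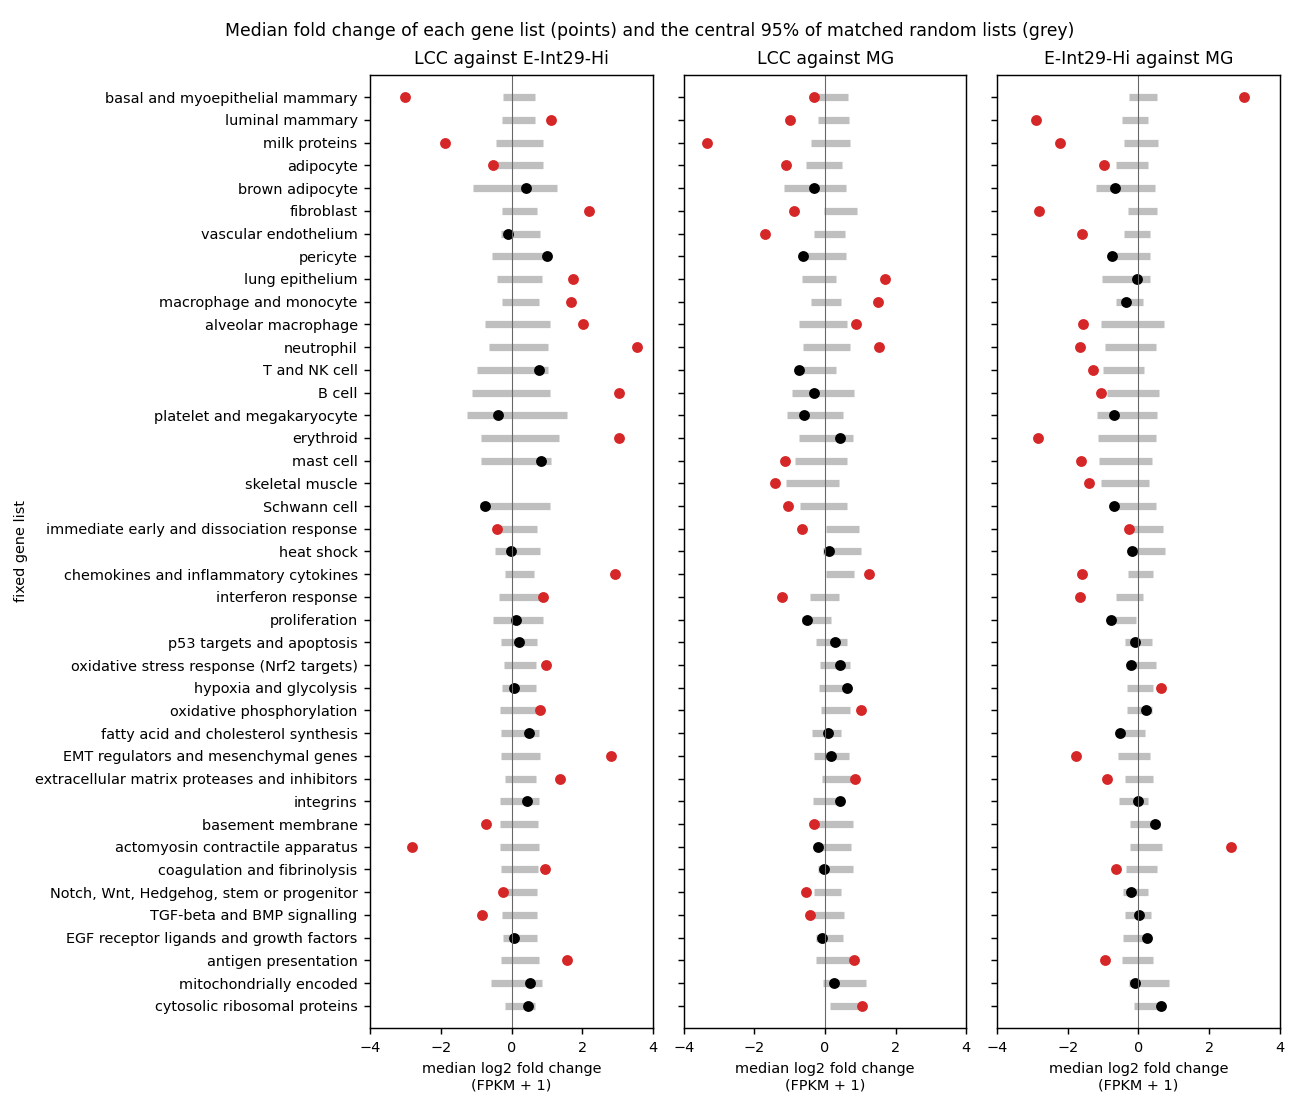
Median log2 fold change (FPKM + 1) of each fixed gene list in the 3 comparisons (points), with bars for the central 95% of 10000 matched random lists and no error bars because there were no replicates. The basal list lies at -3.01 for LCC against E-Int29-Hi and at 3.00 for E-Int29-Hi against MG, and the chemokine list at 2.91 and 1.25 for LCC against E-Int29-Hi and against MG.

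Some genes set a single library at least 4-fold apart from both others. Among 12772 genes at 1 FPKM or more in any library, LCC was higher than both others for 126 and lower for 75. E-Int29-Hi was higher for 254 and lower for 185, and MG was higher for 148 and lower for 8. The genes higher in LCC than in both others included Csf2, Cxcl3, Cxcl5, Ccl2, Mmp3, Mmp12, Inhba, Serpinb2, Timp1, Scgb1a1 and Sftpc. Of these, Csf2 (log2 change -3.54), Cxcl3 (-4.82), Cxcl5 (-4.45), Ccl2 (-4.19), Mmp3 (-5.32), Mmp12 (-2.64) and Serpinb2 (-2.10) were also lower in E-Int29-Hi than in MG.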

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

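All tests of explanations in this part were chosen only after the result was seen. Several genes left out because at least 1 library's value had a status other than OK stood at 10 FPKM or more in E-Int29-Hi and at least 4-fold above MG. In E-Int29-Hi, LCC and MG, Vegfa stood at 766, 222 and 140.2 FPKM, Sox4 at 272, 29.5 and 32.2 FPKM, and Runx1 at 250.5, 59.8 and 53.5 FPKM. Egr2 stood at 137, 25.2 and 17.3 FPKM, Dusp7 at 134, 55.0 and 17.1 FPKM, and Fhod3 at 49.3, 2.52 and 1.296 FPKM. The doubtful status belonged to E-Int29-Hi for Dusp7, Egr2 and Fhod3, to LCC for Runx1, to E-Int29-Hi and MG for Vegfa, and to each library for Sox4. No explanation of these values was tested.

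Lung epithelial transcripts stood out in LCC, although its sort was for the label carried by injected cells; of 16 compared members of the fixed list, 7 stood at least 4-fold above both other libraries, where the upper bound of the central 95% of matched random lists was 1, and 7 of the list's 19 measured genes stood at 1 FPKM or more in MG. A greater depth of LCC is argued against as the cause, because the other libraries resolved lower levels than LCC. Olfactory receptor genes above 0 had medians of 0.193 FPKM in LCC, 0.0254 in E-Int29-Hi and 0.0237 in MG. Genes listed at 0 numbered 6871, 4984 and 3184 in the same order. The highest olfactory receptor values were 0.365 FPKM in E-Int29-Hi and 1.13 FPKM in MG. The lowest of the 7 lung genes stood at 3.34 FPKM in LCC, but the 4-fold rule itself needs 3 FPKM. That gap was therefore fixed in advance and adds no support. RNA of lung epithelial cells in the sorted fraction may account for the pattern, with Scgb1a1 at 572 and Sftpc at 36.3 FPKM. Expression by the mammary cells themselves stays open, with the lung transcription factor gene Nkx2-1 at 0.177 FPKM, because no library of lung alone was analysed here.

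Transcripts restricted to adipocytes were few in MG, although it was labelled as whole gland. The median of 9 adipocyte-restricted genes, picked from the fixed adipocyte list after its values were seen, was 1.12 FPKM. The median of all 21 genes of the fixed list was 6.10 FPKM, with Fabp4 at 845 and Cd36 at 152 FPKM, against 110.5 FPKM for the fibroblast list and 38.5 FPKM for the endothelium list. A scale common to the whole MG library would lower all lists alike, so the higher fibroblast and endothelium medians argue against scaling as the cause. The median ratio factor of MG was 1.02, and it does not bear on a difference between lists within MG. A loss of adipocytes before RNA extraction and donor glands with little fat, with Adipoq at 1.12 FPKM, cannot be told apart, because steps before RNA extraction other than the label of no dissociation, and the state of the donors, are not given in the sources used here. The immediate early and dissociation response list had a median level of 235 FPKM in MG, 109 in LCC and 160.0 in E-Int29-Hi, and the heat shock list 109.8, 114 and 179 FPKM, and neither list bears on adipocytes in particular.

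Salivary gland transcripts stood out in E-Int29-Hi, a sort gated on EpCAM and CD29. Neither salivary cells or RNA in the pooled sample nor expression by basal cells at their level in the gland could be decided. Of 12 salivary genes beyond the 3 that led to the list, 5 stood at least 4-fold above both other libraries, namely Amy1 (30.04 FPKM), Dcpp2, Cst10, Dnase1 and Dcpp3. Dcpp2 and Dcpp3 are copies of Dcpp1, which led to the list, so they are not separate support. Muc19, Prol1 and Smr2 were listed at 0 in E-Int29-Hi. Of the 8 of these genes at 1 FPKM or more in E-Int29-Hi, 5 had an MG to E-Int29-Hi ratio under the lowest of 23 basal genes (0.0407). The median of the 8 was 0.0149, but Amy1 stood at 0.124. Dcpp2 and Dcpp3 are again among those 5. Of the list's 15 genes, 1 stood at 1 FPKM or more in MG.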

How the results depend on the processing

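The alternatives that kept genes of every status, left out genes listed at 0 or left out lung and blood cell lists were chosen only after the results were seen. Under these, median ratio scaling, no filter, a 5 FPKM minimum and summed models, each count of genes apart stayed within 1.5 times its value. Without a filter no count could change, because the 4-fold rule with a pseudocount of 1 needs 3 FPKM, so that setting adds no support. Keeping every status brought back only 112 genes, so it could move the larger counts little. Leaving out the lung and blood cell lists removed only their listed genes from the counts. That setting cannot show whether RNA of such cells affected the other genes. For LCC against E-Int29-Hi, LCC against MG and E-Int29-Hi against MG, the genes at least 4-fold apart numbered 1092, 493 and 817. They numbered 2075, 1149 and 1610 with a pseudocount of 0.1, 444, 166 and 297 with 5, and 1666, 1022 and 1393 in TPM. A smaller pseudocount lets more low genes pass by construction. The TPM setting raised the values of each library while the pseudocount and minimum stayed at 1, which also lets more low genes pass by construction. It changed the libraries relative to each other and the genes kept as well, and the part of each in its move was not tested. Genes higher than both others in LCC, E-Int29-Hi and MG numbered 236, 405 and 360 with 0.1 and 55, 104 and 43 with 5, and MG had 357 in TPM. Genes lower than both others numbered 357, 473 and 31 with 0.1 and 20, 64 and 3 with 5, and LCC had 238 and E-Int29-Hi 357 in TPM. Of the list medians over all settings, 605 stayed close, 231 moved and 3 were counted as changing sign. A sign change was counted only for medians outside the central interval of their random lists. Sign changes of the other medians, which can be near 0, were not counted apart and fall among those that stayed close or moved. For LCC against E-Int29-Hi, the adipocyte median went from -0.52 to 0.0647 with a 5 FPKM minimum. The B cell median went from 3.03 over 5 members to -0.10 over 16 without a filter, which lets in members under 1 FPKM, and to -0.11 over 13 in TPM. Over the named genes of the largest changes and the genes in the text in each comparison, 1157 log2 changes stayed close, 179 moved and 4 changed sign, all under median ratio scaling and none 4-fold apart. For LCC against E-Int29-Hi, Epcam went from 0.22 to -0.057, Cdh5 from 0.16 to -0.108 and Pcna from 0.14 to -0.13, and for E-Int29-Hi against MG Ccl17 went from -0.0058 to 0.093. The correlations moved in 4 of 6 cases. For LCC against E-Int29-Hi, LCC against MG and E-Int29-Hi against MG they were 0.710, 0.820 and 0.799 with a pseudocount of 0.1 and 0.642, 0.773 and 0.724 with a 5 FPKM minimum, so their order was kept. Genes at 5 FPKM or more numbered 7752 in LCC, 7088 in E-Int29-Hi and 7944 in MG. Depth limits genes near 1 FPKM and those listed at 0. No paired analysis was possible because each group has 1 library.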

Other observations

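The mature dendritic cell list in this part was chosen only after the result was seen. Oxidative phosphorylation genes had a median log2 change of 1.02 for LCC against MG (99.99th percentile) and 0.81 against E-Int29-Hi, with 0 of 23 members 4-fold apart in either. Cytosolic ribosomal protein genes had a median of 1.04 for LCC against MG (99.5th percentile), and their near-identical pseudogenes make single values uncertain. Antigen presentation genes had 5 of 18 members higher in LCC than in E-Int29-Hi and 0 lower, with the class II chaperone gene Cd74 at 492 against 59.5 FPKM. Of 24 hypoxia and glycolysis genes, 3 were higher in E-Int29-Hi than in MG, namely Slc2a1, Car9 and Slc16a3, and 0 lower. Of 21 TGF-beta and BMP signalling genes, 5 were lower in LCC than in E-Int29-Hi and 1, Inhba, was higher, with the activin antagonist gene Fst at 11.97 against 228 FPKM.

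A list of 12 genes of mature dendritic cells was written after Ccl17, Ccl22, Il12b and Il23a had been seen. Of its 8 other genes, 1, Traf1, stood at least 4-fold higher in LCC than in both others, at 37.2 FPKM in LCC and 6.76 FPKM in MG. The median log2 change of these 8 was 1.65 against MG and 2.40 against E-Int29-Hi. Of the 12 genes, 8 stood at 1 FPKM or more in MG. The source of these transcripts was not tested.

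Lars2, a mitochondrial leucyl-tRNA synthetase gene, stood at 2377, 86.9 and 30.7 FPKM in LCC, E-Int29-Hi and MG. Gm10180, chosen after its values were seen, stood at 12081, 3344 and 2679 FPKM. Uck2 and 5730522E02Rik were the 2 gene names listed at 0 in LCC with 10 FPKM or more in both other libraries, and there were 0 such genes for E-Int29-Hi and 0 for MG.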
